A study of Mus musculus with 4 samples.

How the data were processed

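Chromatin accessibility in single PB3 mouse mammary tumor cells was measured in 4 libraries, which formed 4 groups of 1 library each: untreated and eribulin cells by scATAC (run 1), and untreated and eribulin nuclei by the ATAC part of a multiome assay (run 3). Groups were taken from the sample titles and treatment labels. Per the series' design text, peak count matrices were made with cellranger-atac 1.2.0 for run 1 and cellranger-arc 1.0.0 for run 3 on the mm10 reference, and were analysed with Signac 1.1.1. Per the submitters' processing notes, Cell Ranger 3.1.0 and 4.0.0 were also used in the study.

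Per the series' design text, cells with fewer than 1000 or more than 75000 fragments in peaks, a nucleosome signal above 10 or an enrichment at transcription start sites below 2 were removed, as were cells failing limits of 20% for the share in peaks and 0.05 for the blacklist ratio. Clusters and the UMAP were made from components 2 to 30 of a latent semantic indexing of the peaks. How the libraries were integrated and how barcodes were called is not given in the sources used here. In the deposited cells the nucleosome signal stayed below 2 throughout, and 1 cell exceeded 75000 cut sites, with 82683.

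The files used here were a table of 43782 cells, a table of their UMAP coordinates and a list of lentiviral barcodes. The deposited counts are whole numbers of Tn5 cut sites in peaks, of peaks detected, of gene activity totals and of genes detected per cell, without normalization. The deposited nucleosome signal is a ratio per cell of fragments as long as 1 nucleosome to nucleosome-free fragments, and the deposited TSS enrichment is a ratio of cuts at transcription start sites to cuts in their flanks, both named as Signac names them per the file headers. The deposited percentile columns give each cell's rank as a fraction and were not used for a comparison. The deposited UMAP axes are a score without unit. The deposited cluster numbers come from a neighbour graph on the peaks at resolution 0.8. Of the 37 columns of the cell table, 16 were empty or 0 in every cell, among them the RNA counts and pseudotime. Values of single genes or peaks were not analysed here, so no gene is named and clusters are given by number, as the rule set before the data were examined requires. Described in full are clusters with at least 10% of any library or a difference of at least 5 percentage points within either protocol.

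From these tables the shares of cells per cluster, the eribulin minus untreated differences within each protocol, medians and quartiles over cells, neighbour shares on the UMAP and barcode shares were computed. The tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No test between groups was made, as set before the data were examined: each group is 1 library, cells are not replicates, and the 2 runs give 2 pairs of libraries, which leave 1 residual degree of freedom in a model of treatment and run and allow no two-sided exact p below 0.5. Shares carry exact 95% binomial (Clopper-Pearson) intervals, ratios of barcode shares carry exact intervals for the ratio, and a count of 0 is given the limit of 3 counts. These cover counting error only. Neighbour shares used 30 neighbours in libraries thinned to equal numbers of cells with a fixed seed. The number of distinct barcodes at matched depth is the exact expected number in a random draw of called cells without replacement. Its SD comes from 2000 random draws. For 1 explanation weighed in the closing section, the barcodes of the eribulin scATAC library were dealt at random to its called cells 1000 times, which gives a range for that library and no test of treatment. The calculations of barcode diversity and of same-barcode pairs were tested on simulated data with 7 known quantities. The least accurate came within 4.52% of its true value. The simulated barcodes were equally frequent, unlike the real ones, and the other calculations were not simulated.

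Barcodes were compared among cells with a single called barcode. Negative cells, and cells called doublet, multiplet or unmapped, were left out of these comparisons and kept in all others. In the untreated multiome library 669 cells were called doublet and 196 multiplet, in the eribulin one 56 and 6. In scATAC 1 untreated and 5 eribulin cells were called doublet and none multiplet. The list held 10000000 barcodes of 48 bases, made of 100 short parts of 14 bases and 100000 long parts of 30 bases joined by the linker TGGT at bases 15 to 18 from the first base. Barcode names were written with hyphens, without hyphens or with the sequence, depending on the library. They were brought to 1 form by the numbers of the short and long part. All 490 barcodes seen were in the list, and the sequence given for 372 eribulin multiome cells matched the list in 372 cases. The barcodes named are the 5 most frequent in the eribulin multiome library and frequent ones of the untreated multiome library, a choice made after their counts were seen.

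The alternatives tried were the stated limits on cells, a range of cut sites shared by both libraries of a protocol (4802 to 9864 in scATAC and 3484 to 7439 in the multiome libraries), means in place of medians, 10 or 100 neighbours, barcodes of at least 3 cells, and, for the barcode list, distinct sequences or a random sample of 100000 entries. Added after the data were seen were the removal of cells called doublet or multiplet, pooled clusters, single forms of barcode name, and the shared range of cut sites for quality values and barcode pairs.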

Results

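Chromatin accessibility was measured in single PB3 cells, a mouse mammary tumor cell line, without treatment and after repeated exposure to eribulin, a drug that blocks microtubule growth. The treated cells had received 500 nM eribulin for 72 h followed by 48 h of recovery, for 4 rounds in all. Each condition was profiled by 2 protocols, single-cell ATAC-seq (scATAC) in run 1 and the ATAC part of a single-nucleus multiome assay in run 3. In ATAC-seq the Tn5 transposase cuts accessible DNA, so that the cut sites in peaks mark open chromatin. There was 1 library per condition and protocol, so the spread between replicates of a group could not be measured. No test of treatment was made: the runs form 2 matched pairs of untreated and eribulin libraries, for which an exact two-sided permutation test cannot give a p below 0.5. The scATAC libraries held 9361 untreated and 16724 eribulin cells, with 84615925 and 127710435 cut sites in peaks. The multiome libraries held 9583 untreated and 8114 eribulin cells, with 61629245 and 49446970 cut sites in peaks. Eribulin was compared with no treatment within each protocol, and the second protocol served as a repeat. Whether both runs used the same treated culture is not given in the sources used here, so the repeat may be of the assay alone. Intervals are exact 95% binomial (Clopper-Pearson) intervals unless another is named, and they cover counting error only, not the difference between cultures.

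The first comparison asked whether eribulin altered the chromatin state of the tumor cells. Untreated and eribulin-treated cells fell into almost separate sets of chromatin clusters in both protocols. Of the 17 clusters that the authors defined on the joint data, 9 held a larger share of the eribulin library in both protocols, and the other 8 held a larger share of the untreated library in both. The 9 eribulin clusters (0, 1, 5, 7, 10, 11, 12, 13 and 15) contained 99.4% (99.3 to 99.5) of the eribulin scATAC cells and 1.34% (1.11 to 1.59) of the untreated ones. In the multiome libraries the same clusters contained 98.4% (98.1 to 98.7) of the eribulin cells and 1.76% (1.51 to 2.05) of the untreated cells. Cluster 15 was the most mixed of the 9, with 76.0% of its 580 cells from eribulin libraries against at least 98.3% in each of the others, and its eribulin scATAC cells had a median of 19698 cut sites.

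Untreated cells were spread over clusters 2, 3, 4, 6, 8, 9 and 14. Cluster 3 held 17.5% of the untreated scATAC cells and 18.4% of the untreated multiome cells, and cluster 6 held 15.2% and 14.7%. Cluster 8 held 13.5% and 11.7%, cluster 9 held 13.0% and 11.6%, and cluster 14 held 5.86% and 4.82% of these libraries. In the eribulin libraries each of these 5 clusters held at most 0.320% of the cells. Clusters 4 and 2 were each frequent in only 1 protocol. Cluster 4 held 31.2% (30.3 to 32.2) of the untreated scATAC cells and 0.960% of the untreated multiome cells, whereas cluster 2 held 1.35% and 34.6% (33.6 to 35.5).

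Eribulin-treated cells occupied different clusters in the 2 protocols. In scATAC, cluster 1 held 35.8% (35.1 to 36.5) of the eribulin cells, cluster 5 held 17.2% and cluster 7 held 15.7%. These 3 clusters held 0.234%, 0.111% and 0.123% of the eribulin multiome cells, and none of the 9583 untreated multiome cells, which allows a share of up to 0.0313% each. In the multiome library 78.5% (77.6 to 79.4) of the eribulin cells lay in cluster 0, which held 0.771% of the eribulin scATAC cells, 0.256% of the untreated scATAC cells and 0.428% of the untreated multiome cells. Clusters 10, 11 and 12 were occupied in both eribulin libraries. Cluster 10 held 9.17% of the eribulin scATAC cells and 3.41% of the eribulin multiome cells, cluster 11 held 8.11% and 4.56%, and cluster 12 held 5.56% and 6.74%. Their untreated shares lay between 0.010% and 0.214%. Cluster 13 held 6.32% of the eribulin scATAC cells and 1.06% of the eribulin multiome cells.

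**Figure D1:**
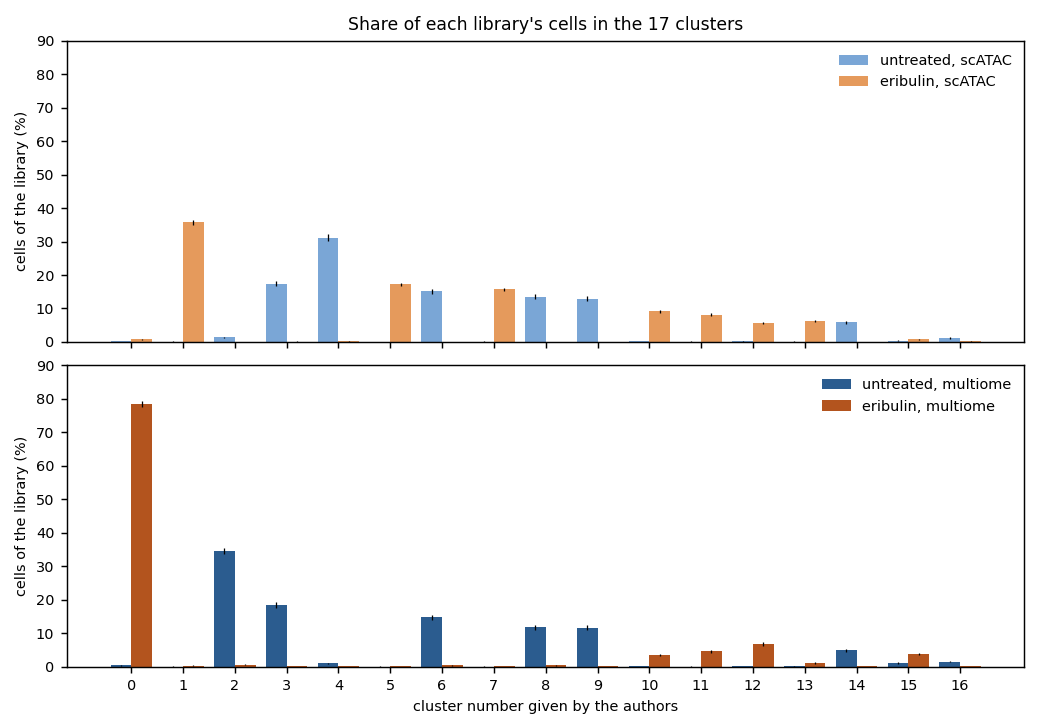
Share of each library's cells (%, vertical axis) in the 17 clusters given by the authors (horizontal axis), with scATAC in the upper and multiome in the lower panel; error bars are exact 95% binomial intervals for counting error. Clusters with tall eribulin bars have almost no untreated cells and the reverse, and cluster 0 holds 78.5% of the eribulin multiome cells.

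All 17 clusters differed in the same direction in both protocols. Unrelated directions would give 8.5 on average, a value that does not allow for clusters drawn on the joint data, and clusters 1, 5 and 7 rest on 19, 9 and 10 eribulin multiome cells against 0 untreated ones. The overlap of the cluster shares, the sum over clusters of the smaller of both shares, was 1.93% between eribulin and untreated cells in scATAC and 3.33% in the multiome libraries. Between protocols it was 64.6% for untreated cells and 17.0% for eribulin cells. With clusters 2 and 4 pooled the untreated value was 94.9%, and with clusters 0, 1, 5 and 7 pooled the eribulin value was 85.2%. Both poolings were chosen after the shares were seen and join clusters frequent in only 1 protocol, which raises the overlap by construction. The clusters were built on all 4 libraries together, so that a cluster made mostly of 1 library can reflect that library as well as a chromatin state. In only 5 of the 17 clusters (3, 6, 8, 9 and 12) was the difference at least 5 percentage points in both protocols. Cluster 12, the only eribulin cluster among these 5, fell below that size among cells in the range of cut sites shared by both scATAC libraries, where its scATAC difference was 3.04 points in place of 5.39.

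The deposited UMAP, a map that places cells of like accessibility close together, showed the same separation. It was made from the same components of the peaks as the clusters, so it gives no independent evidence. After both libraries were thinned to the same number of cells, 95.9% of the 30 nearest neighbours of a cell came from its own treatment in scATAC and 92.8% in the multiome libraries, where complete mixing gives 50.0%. Between protocols 60.4% of the neighbours of untreated cells and 82.2% of those of eribulin cells came from the cell's own library.

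**Figure D2:**
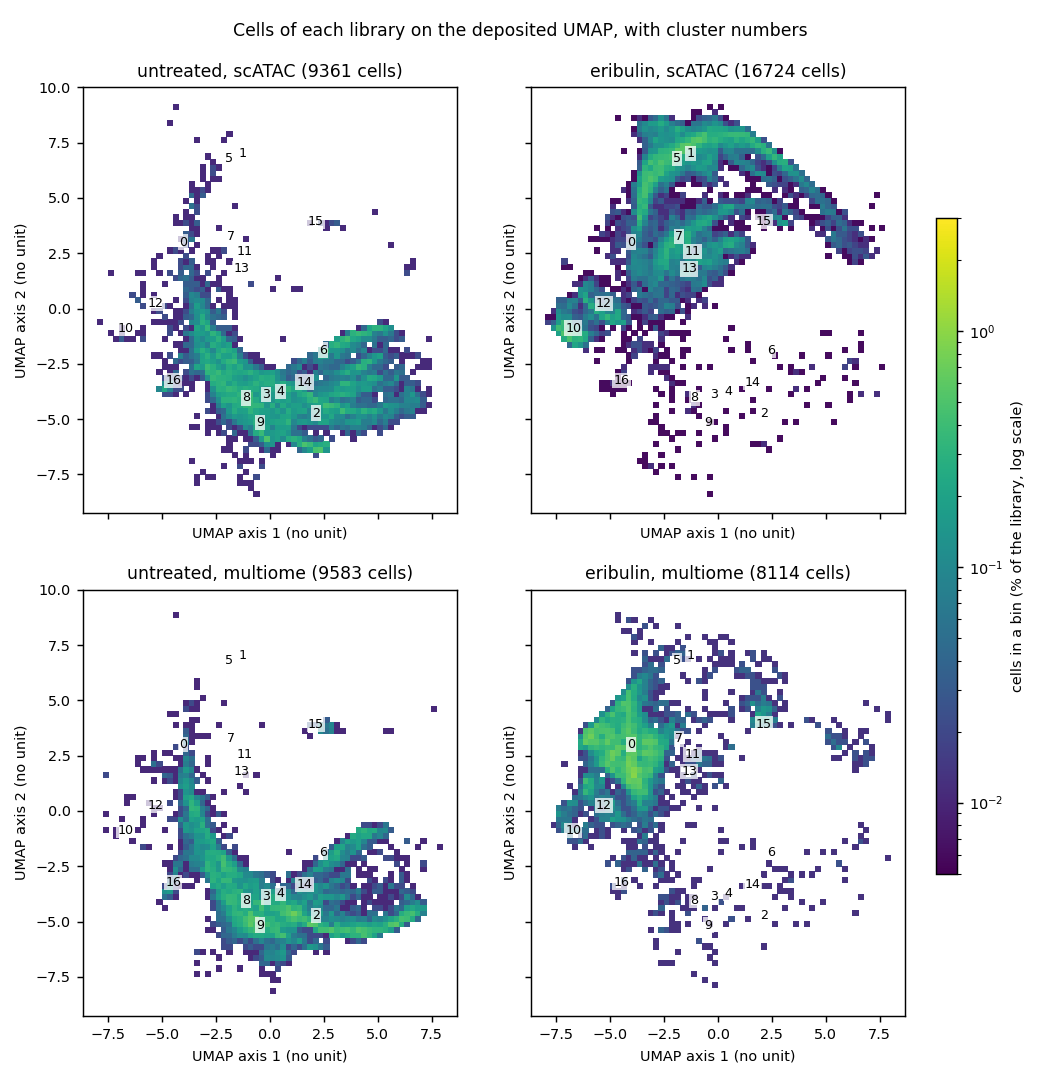
Cells of each library on the deposited UMAP (both axes without unit), with colour giving the share of the library's cells in each bin on a log scale and numbers marking the median position of each cluster. Untreated cells of both protocols fill the lower arc. Most eribulin cells lie above it, around clusters 1, 5 and 7 in scATAC and around cluster 0 in the multiome library, and those of clusters 10 and 12 lie to its left.

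The next comparison concerned the packing of the accessible DNA. Eribulin cells had a lower nucleosome signal, the ratio of fragments as long as 1 nucleosome to shorter, nucleosome-free fragments. Its median was 1.07 (quartiles 0.984 and 1.16) in untreated and 0.756 (0.692 and 0.824) in eribulin scATAC cells, a change of -29.3%. In the multiome libraries it was 0.907 (0.816 and 1.01) in untreated and 0.668 (0.607 and 0.739) in eribulin cells, a change of -26.3%. In scATAC 98.6% of the eribulin cells lay below the untreated median, as did 96.1% in the multiome libraries.

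The lower signal was found in each of the main eribulin clusters. Only cluster 15, in the multiome libraries, had at least 50 cells of both treatments within a protocol. The medians of the other clusters therefore cannot show a difference between treatments within a cluster. Among clusters with at least 50 cells of a library, and apart from cluster 15, the median nucleosome signal was 1.02 to 1.14 in untreated and 0.724 to 0.811 in eribulin scATAC cells. In the multiome libraries it was 0.846 to 0.983 in untreated and 0.661 to 0.678 in eribulin cells. The median of cluster 15 was 1.72 in eribulin scATAC, 1.27 in untreated multiome and 0.652 in eribulin multiome cells. The enrichment of cut sites at transcription start sites hardly differed, with medians of 4.99 and 5.04 in untreated and eribulin scATAC cells and 5.01 and 5.07 in the multiome libraries. Eribulin cells were shallower, with a median of 6049 against 7440 cut sites in scATAC and 4229.5 against 5217 in the multiome libraries. For the multiome libraries the difference of -987.5 cut sites between medians became -337 between means. Fragment length ratios depend on each library's transposition and size selection, which 1 library per group cannot separate from treatment.

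Lentiviral barcodes, heritable DNA tags that mark the descendants of an infected cell, allowed the lineages present with and without eribulin to be compared. Among cells with a called barcode, 5 barcodes that each had at most 0.838% of the untreated multiome cells were frequent in the eribulin libraries. Together these 5 accounted for 89.4% (87.7 to 91.0; 1244 of 1391) of the eribulin multiome cells with 1 called barcode, and for 1.66% (1.31 to 2.06; 79 of 4772) of the untreated ones. In scATAC the same 5 barcodes, chosen on the multiome counts, accounted for 95.2% (88.3 to 98.7; 80 of 84) of the called eribulin cells and 6.90% (0.846 to 22.8; 2 of 29) of the called untreated cells. A single barcode was called in 49.8% of the untreated and 17.1% of the eribulin multiome cells, but in only 0.310% and 0.502% of the scATAC cells. The called eribulin multiome cells differed from their library: their median was 5957 cut sites against 3914 in cells called negative, 63.0% of them lay in cluster 0 against 78.5% of the library, and 17.2% lay in cluster 12 against 6.74%.

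Barcode 76-49517, named by its short and long part and with the sequence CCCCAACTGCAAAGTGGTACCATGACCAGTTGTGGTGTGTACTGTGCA, was the most frequent in the eribulin multiome library. It was called in 438 cells (31.5%, 29.1 to 34.0) there and in 2 untreated multiome cells (0.042%), a ratio of 751 (exact interval 207 to 6223). Barcode 6-93034, with the sequence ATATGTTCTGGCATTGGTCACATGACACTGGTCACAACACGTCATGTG, was called in 403 eribulin cells (29.0%) and 12 untreated cells (0.251%), a ratio of 115 (65.2 to 225). Barcode 95-33662 was called in 176 and 6 cells, a ratio of shares of 101 (45.3 to 278), and barcode 55-23349 in 146 and 19 cells, a ratio of 26.4 (16.3 to 45.0). Barcode 39-41529 was called in 81 eribulin and 40 untreated cells, a ratio of 6.95 (4.70 to 10.4). The order of the barcodes depended on the form in which their names were written: 76-49517 had 36.7% of the eribulin multiome cells named with hyphens and 17.2% of those named with a sequence, whereas 55-23349 had 5.99% and 22.8%. The same barcodes had 25, 8, 6, 30 and 11 of the 84 called eribulin scATAC cells, in this order. In the untreated scATAC library the first 4 had 0 of 29 cells, which allows a share of up to 10.3%, and the last had 2. The exact interval of the scATAC ratio lay above 1 for 76-49517 (from 2.17) and 55-23349 (from 2.64). It included 1 for 6-93034 (from 0.589), 95-33662 (from 0.406) and 39-41529 (0.414 to 17.6).

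**Figure D3:**
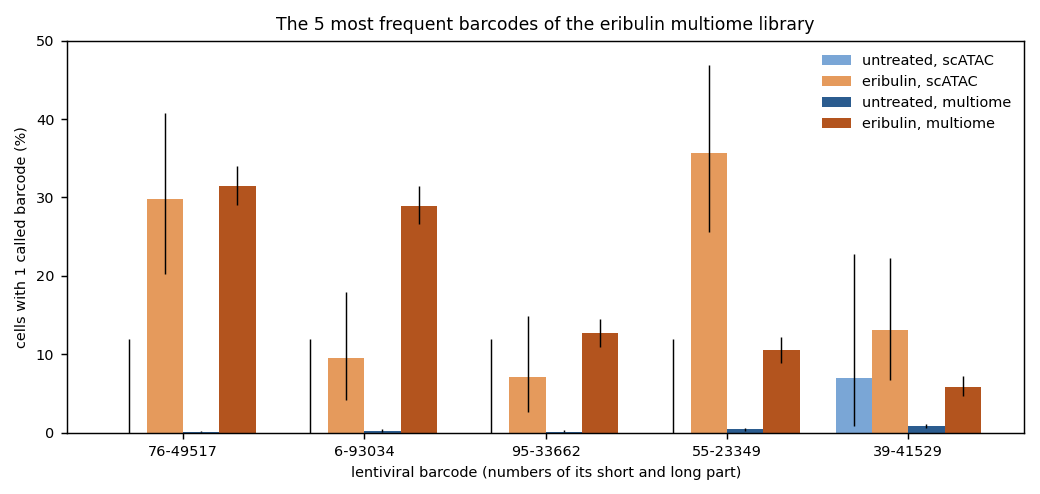
Share of the cells with 1 called barcode (%, vertical axis) that carried each of the 5 most frequent barcodes of the eribulin multiome library (horizontal axis), in all 4 libraries; error bars are exact 95% binomial intervals. The barcodes are frequent in both eribulin libraries, and each has at most 0.838% of the called untreated multiome cells.

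Barcodes frequent without treatment were mostly not detected after eribulin. Barcode 22-14328, the most frequent untreated one with 182 multiome cells (3.81%, 3.29 to 4.40), was called in none of the 1391 eribulin multiome cells. That count allows a share of up to 0.216%, at least 17.7-fold below the measured 3.81%, whose own counting error this factor leaves out. Of the 10 most frequent untreated multiome barcodes, only 95-65716 was found in eribulin multiome cells, in 2 of them. The 10 barcodes had 8 of the 29 called untreated scATAC cells and 0 of the 84 called eribulin scATAC cells. Of 125 barcodes with at least 10 untreated multiome cells, 107 (85.6%) had no eribulin multiome cell. For the least frequent of these, a count of 0 does not show a lower share, because it allows up to 0.216%. The number of such counts without any change of shares was not computed.

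Barcode diversity was lower in the eribulin libraries. The untreated multiome library had 484 distinct barcodes and the eribulin one 27. With the untreated library drawn down to 1391 called cells, 330 distinct barcodes remained on average. The effective number of barcodes, the inverse of the chance that 2 cells share a barcode, was 118 in untreated and 4.65 in eribulin multiome cells. In scATAC 24 distinct barcodes were found in 29 untreated cells, against an average of 5.96 in 29 of the 84 eribulin cells. Of the 24 untreated scATAC barcodes 20 were seen in 1 cell, so that a minimum of 3 cells per barcode left 1 of them and 6 of the 7 eribulin scATAC barcodes. With that minimum the direction of the scATAC difference was reversed. Of the 27 eribulin multiome barcodes, 25 were also found in the untreated multiome library, and all 7 eribulin scATAC barcodes were found in the eribulin multiome library. The names of the barcodes took different forms in the libraries, and in the eribulin multiome library the 5 barcodes had 96.8% of the 1019 cells named with hyphens and 69.4% of the 372 named with a sequence.

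The barcodes were then set against the clusters. In the untreated multiome library, cells of 1 barcode lay largely in the same cluster. Pairs of cells with the same barcode shared a cluster in 59.7% of cases, and pairs with different barcodes in 21.1%; with the 125 barcodes of at least 10 cells weighted equally, the same-barcode share was 49.5%. Of these 125 barcodes, 107 had over 50% of their cells in a single cluster. Over all 125 barcodes, the share in the cluster with most of a barcode's cells had a median of 69.2% (range 27.3% to 91.7%). That cluster was each barcode's own most frequent one, chosen on the same cells, which raises these shares where cells are few. Cluster 2, which held 34.6% of the library, was the most frequent one for 56 of the barcodes. The scATAC libraries, with few called cells, did not show this relation. Of 18 untreated scATAC cells whose barcode had at least 10 untreated multiome cells, 2 lay in the main multiome cluster of their barcode with clusters 2 and 4 taken as 1, and 0 with them apart. The library's cluster shares alone would give 3.37 of the 18, and the multiome cells of the same barcodes 14.1. The latter number rests on clusters chosen on those same multiome cells and may be too high.

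Single barcodes of the untreated multiome library showed the relation. Barcode 22-14328 had 76.4% (69.5 to 82.3) of its cells in cluster 14, which held 4.82% of the library. Barcodes 50-60095 and 30-58918 had 83.9% and 88.7% of their cells in cluster 6, which held 14.7%. Barcode 71-53519 had 91.7% (82.7 to 96.9) in cluster 2, barcode 92-83570 had 85.1% (74.3 to 92.6) in cluster 9, barcode 55-6980 had 70.7% in cluster 8, and barcode 52-92557 had 68.1% in cluster 3.

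Barcodes also differed in their clusters among eribulin multiome cells. Same-barcode pairs shared a cluster in 56.8% of cases and different-barcode pairs in 39.7%, but with the 10 barcodes of at least 10 cells weighted equally the same-barcode share was 44.2%. Barcodes 76-49517 and 55-23349 had 83.8% (80.0 to 87.1) and 83.6% (76.5 to 89.2) of their cells in cluster 0, which held 78.5% of the library, and 53.4% and 60.6% of the cells of the respective other barcodes. Barcode 6-93034 had 49.6% (44.6 to 54.6) of its cells in cluster 12, against 3.95% of the cells of other barcodes. Barcode 95-33662 had 33.0% (26.1 to 40.4) of its cells in cluster 10, against 2.06%, and barcode 39-41529 had 42.0% (31.1 to 53.5) in cluster 11, against 2.44%. In the untreated multiome library 34 of the 40 cells of barcode 39-41529 (85.0%, 70.2 to 94.3) lay in cluster 2, whereas barcode 55-23349 had 8 of 19 cells in cluster 3 and barcode 6-93034 had 5 of 12 in cluster 6. Among eribulin scATAC cells same-barcode pairs shared a cluster in 23.7% of cases and different-barcode pairs in 23.6%. There, barcode 6-93034 had 1 of 8 cells in cluster 12. The 6 cells of 95-33662 lay in clusters 1, 5 and 12, and the 11 cells of 39-41529 in clusters 1, 7 and 10.

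**Figure D4:**
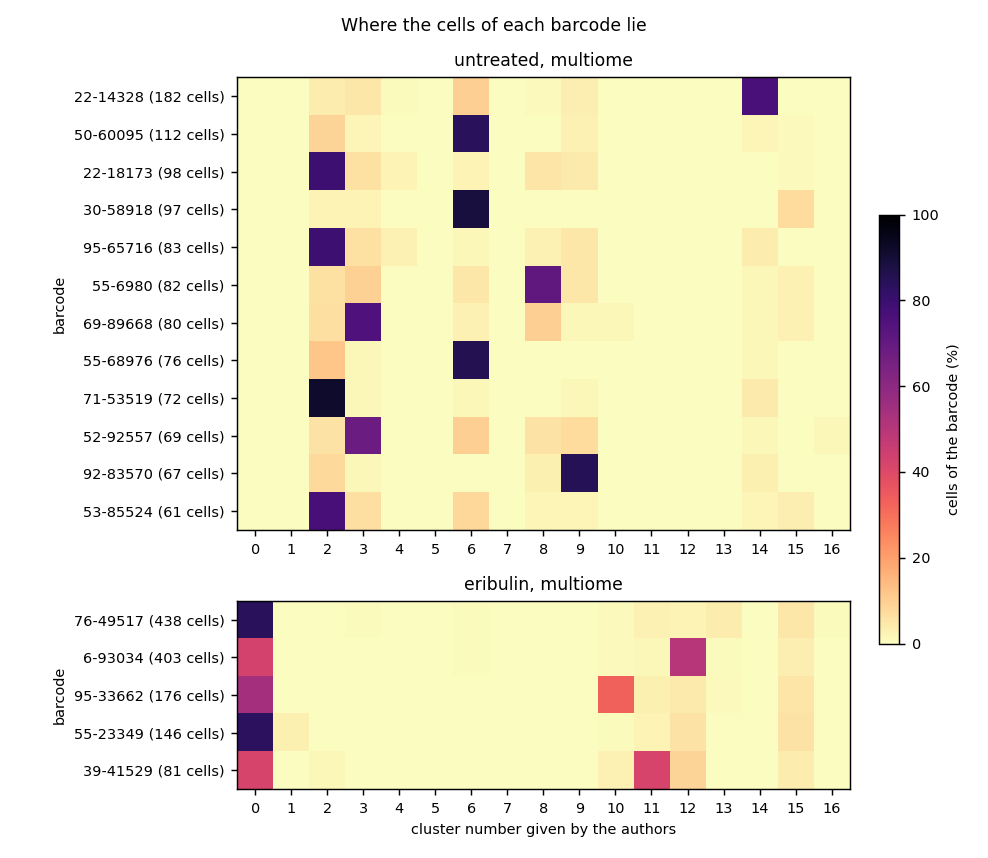
Share of the cells of each barcode (%, colour) in each of the 17 clusters (horizontal axis), for the 12 most frequent barcodes of the untreated multiome library (upper panel) and the 5 most frequent of the eribulin multiome library (lower panel), with the number of cells beside each barcode. Most untreated barcodes have 1 dark cell in the row, such as cluster 14 for barcode 22-14328 (76.4%), and of the 5 eribulin barcodes, 76-49517 and 55-23349 lie mainly in cluster 0 (83.8% and 83.6%) while the other 3 divide between cluster 0 and cluster 12, 10 or 11.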

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

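The shared range of cut sites, means, other numbers of neighbours, stated limits, differences of at least 5 points, and the minimum of 3 cells were fixed before the data were examined; pooled clusters, forms of name, removal of cells called doublet or multiplet, and the shared range for nucleosome signal and barcode pairs were chosen afterwards. Over all results and alternatives 206 values were recomputed, of which 166 stayed within tolerance, 39 moved and 1 reversed. The tolerance was the counting interval for a share, 1.5 times for a number of cells, clusters or barcodes, 1 percentage point for neighbour shares, 0.5 points for the base content of the barcode list, and a range over resampled cells or barcodes for quality values, overlaps and barcode pairs. The stated limits removed 1 cell, and 1 and 5 scATAC cells were called doublet, so the former in both protocols and the latter in scATAC could hardly move a cluster difference and say little of stability. In the multiome libraries, where 669 and 56 cells were called doublet and 196 and 6 multiplet, the cluster differences without these cells stayed within tolerance. In the shared range of cut sites 14 of the 34 cluster differences moved, among them those of clusters 0, 12 and 15 in scATAC (to 0.171, 3.04 and 0.134 points) and of clusters 7, 13 and 16 in the multiome libraries (to 0, 1.83 and -0.883 points), and 16 of the 17 clusters had the same direction in both protocols. Differences of at least 5 points in both protocols left 5 clusters. In the shared range, the overlap between protocols of eribulin cells was 14.2%, own-library neighbours were 97.3% (scATAC treatment), 95.7% (multiome treatment) and 88.1% (eribulin between protocols), the multiome nucleosome signal differed by -0.257 in place of -0.239, and same-barcode pairs of the untreated multiome library shared a cluster in 68.1%. With 100 neighbours, untreated cells had 59.1% of neighbours in their own library. Pooling clusters 2 and 4 raised the untreated overlap between protocols to 94.9%, and pooling clusters 0, 1, 5 and 7 raised that of eribulin cells to 85.2%, both by construction. As a mean over cells, the multiome difference in cut sites was -337, and the multiome difference in gene activity total over cut sites in peaks turned to 0.00771 from -0.00535. The cause of the other shifts was not tested. A minimum of 3 cells per barcode leaves fewer barcodes by construction. Untreated scATAC then kept 1 distinct barcode (effective number 1.0, 1.0 at matched cells) and eribulin scATAC 6 (effective number 3.93, 2.33 at matched cells). The scATAC difference between treatments thus reversed, which the count of reversed values leaves out because each library was labelled alone. The matched number was here the cells of the 1 untreated barcode left, not all 29 called cells. Untreated multiome kept 290 distinct barcodes, and eribulin multiome 13 distinct and 13 at matched cells. Among names with a sequence the eribulin multiome library had 11 distinct barcodes and an effective number of 7.24. The scATAC barcodes rest on 29 and 84 called cells. Not run were shares over promoters, enhancers and other regions, pseudotime and phase values, gene values, and the limits on the share in peaks and the blacklist ratio, which have no filled column in the tables used here; the other cluster column is identical (0 cells differ). With 1 library per group none could be left out.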

Other observations

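The explanations weighed in this part, their tests and the barcodes named were chosen after the results they bear on had been seen; the numbers of barcodes and the cluster shares of each library had been planned.

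Cells of rare barcodes in the eribulin multiome library lay more often in clusters of untreated cells than those of frequent barcodes did. Among barcodes with fewer than 10 cells there, 12 of 39 cells (30.8%, 17.0 to 47.6) lay in the 8 clusters that untreated cells occupied, against 26 of 1352 cells (1.92%, 1.26 to 2.81) of barcodes with at least 10 cells. All 17 of these rare barcodes were also found in the untreated multiome library, as were 8 of the 10 barcodes with at least 10 cells. Barcode 55-98358, with 46 eribulin multiome cells (3.31%, 2.43 to 4.39), was called in 0 of the 4772 untreated multiome cells, which allows a share of up to 0.0629%. Barcodes 55-99383 and 55-37135 showed no difference detectable at this depth, with 12 eribulin against 36 untreated cells (ratio of shares 1.14, 0.542 to 2.25) and 11 against 57 cells (ratio 0.662, 0.313 to 1.28).

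Cells whose barcode call was unmapped were deep, with a median of 16661 cut sites in the untreated multiome library (56 cells, library median 5217) and 15789 in the eribulin one (39 cells, library median 4229.5).

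The first pattern weighed was the smaller number of distinct barcodes in the eribulin libraries. Fewer called cells do not account for it in the multiome libraries, since the untreated library drawn down to the eribulin number of called cells still had 330 barcodes against 27. In scATAC both libraries use 1 form of barcode name, so forms do not account for 5.96 barcodes on average in 29 eribulin cells against 24 in the untreated library, of which 20 were seen in 1 cell. In the multiome libraries, which share no form, an effect of the form cannot be told apart from treatment, although the effective number was at most 7.24 in either eribulin form against 118 in the untreated library. Survival of a few lineages under eribulin, loss of lineages by passaging, and calling that failed more often for some barcodes in the eribulin library (called in 17.1% of cells against 49.8%) were not tested and stay open.

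The second pattern was that the eribulin libraries of both protocols occupied different clusters. For the 84 barcoded eribulin scATAC cells, different barcodes do not account for it, provided that these barcodes are set to the right cells. Placed as the multiome cells of the same barcodes were, 70.5% of the 84 would lie in cluster 0, and 1 of them did (1.19%, 0.030 to 6.46). The 84 were 0.502% of their library, of which cluster 0 held 0.771%, so for the remaining cells different barcodes stay open. Different depth does not account for the pattern, since among cells with 3644 to 7439 cut sites the overlap of cluster shares was 15.7%, against 17.0% at all depths. A difference between the runs and protocols stays open, as the untreated libraries overlapped by 64.6%, less than fully but more than the eribulin ones. With clusters 2 and 4, and clusters 0, 1, 5 and 7, pooled the values were 94.9% and 85.2%. These clusters were each frequent in 1 protocol only, so pooling them raises the overlap by construction and cannot decide the question. Whether the eribulin cells came from 1 course of treatment is not given in the sources used here. Protocol and culture cannot be told apart with 1 library each.

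The third pattern was that cells of 1 barcode shared a cluster in the untreated multiome library and not in scATAC. Depth differences between cells do not account for the multiome relation, since among cells of like depth 68.1% of same-barcode pairs and 22.2% of different-barcode pairs shared a cluster. An artifact of the multiome libraries may be the cause, as only 2 of 18 untreated scATAC cells (11.1%, 1.38 to 34.7) lay in the multiome cluster of their barcode, where the multiome cells predict 78.5%. The predicted share may be too high, because each cluster was chosen on those same multiome cells. Barcodes set to the wrong cells in scATAC may also be the cause. Same-barcode pairs of eribulin scATAC cells shared a cluster in 23.7% of cases, within the 20.2% to 27.8% spanned by 95% of random assignments of the barcodes. The share that rightly set barcodes would give in these 84 cells was not computed, so the value cannot decide. All 7 barcodes of the eribulin scATAC library were also found in the eribulin multiome library. Their shares were alike for 76-49517 (29.8% in scATAC and 31.5% in the multiome library). They differed for 6-93034 (9.52% and 29.0%) and 55-23349 (35.7% and 10.5%). Barcodes exchanged among the cells of 1 library leave its list of barcodes unchanged, so the shared list cannot decide either. Both explanations remain open, so heritable chromatin states of single lineages stay an untested hypothesis.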
